A study of Homo sapiens with 4 samples.

How the data were processed

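The series holds 4 ChIP-exo samples, 2 biological replicates of each of 2 human cell lines, Hs700T (pancreatic tumour) and MCF-7 (breast cancer). Per the labels, cells were transfected with a plasmid for V5-tagged ZNF414 and collected 48 h later, and bound DNA was precipitated with an antibody against the V5 tag. ChIP-exo adds a 5' to 3' exonuclease step to ChIP-seq, so that read ends mark the edge of the crosslinked protein on each strand.

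Per the submitters' processing notes, Bowtie2 2.3.2 and SAMtools 1.3 were used with the hg19 build, with no role given for either. Per the labels, MACE called the borders and merged the replicates of a line into 1 list. The MACE version, its settings, the handling of duplicate reads and any background library are not given in the sources used here. Each deposited list gives the chromosome, start, end, a class and the p-value of each border pair as the authors deposited it, without adjustment and ending at 0.05. The class says whether a forward and a reverse border were both called, here a matched pair, or 1 border alone, here a lone border, to which the caller gave a fixed width. That width was 68 bp for 99.6% of lone borders in Hs700T and 72 bp for 99.0% in MCF-7. The p-value of each pair was used only to describe, rank or filter pairs within its own list. The files hold no read counts, so the depth is unknown, and a list length or a p-value does not show how much sequencing lay behind it.

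All positions are hg19 as in the deposited lists, written from base 1. Pairs on chromosomes 1 to 22 and X were used, which left out 371 pairs of Hs700T and 629 of MCF-7. The mitochondrial pairs among them are described separately, and chromosome Y was not analysed here. Overlap of at least 1 bp was computed with bedtools 2.31.1 and compared with 100 seeded circular shifts of a list along each chromosome and with 100 seeded shifts of 1 to 10 kb, which keep the regional density. The smallest one-sided p-value that 100 shifts can give is 0.0099. Errors of the shared share came from a jackknife over 5 Mb blocks and those of border distances from a jackknife over the 23 chromosomes. These describe variation along the genome and not between replicates. Distances between borders used the start of each pair with a forward border and the end of each pair with a reverse border.

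Pairs were counted by their centre in 1 Mb windows. The log2 ratio of MCF-7 to Hs700T, after adding 1 to both counts, was scaled by the list totals, and windows with fewer than 10 pairs in the higher line were left out. Intervals of window ratios are exact Clopper-Pearson 95% intervals on the share of MCF-7 among the pairs of a window, and cover counting error only. The slope of matched pairs on lone borders came from a Poisson regression on the log scale over windows with at least 20 lone borders. The analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

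The steps were tested on simulated lists with the real window densities and 746272 Hs700T pairs. With no shared site planted, the share was 1.01 times that after shifts. With 10 percent of sites planted, an excess of 9.46 percentage points was recovered as 9.49, and 37982 planted borders at the same base as 37976. A 3-fold gain of 40 windows, a log2 change of 1.58, was recovered as 1.54. Chance pairing of borders over 2868 windows, with a slope of 2, gave 2.02.

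The strong set was to hold the 20000 pairs of smallest p per list, with ties left out where they took it over 30000. Ties at a p of 0.00503 did so in both lines, which left 13850 pairs in Hs700T and 13509 in MCF-7, all matched pairs. Promoters, gene lists, annotation classes, sequence motifs and repeats were planned but need a genome or annotation of hg19, which was not used here. A RefSeq gene table of another assembly served only for the chromosome of named genes, and no gene was placed by position. The rule for genes, fixed before the data were examined, named 1 Mb windows instead: in each line the 10 with the smallest p (ties by more pairs) and the 10 with most pairs, and the 10 with the highest and the lowest ratio between the lines. The alternatives planned at the same time were stricter p limits of 0.01 and 0.001, merged pairs, other overlap rules, the strong set, leaving out the 1% densest windows of either list, a shortened MCF-7 list and 5 Mb windows. The comparison by class of pair, the borders at the same base, the slope of matched pairs, the runs of windows, matched pairs alone and scaling by the median window were not in that plan and were added after the files had been opened.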

Results

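ChIP-exo of V5-tagged ZNF414, a zinc finger protein overexpressed from a plasmid, was carried out in Hs700T, a human pancreatic tumour line, and in MCF-7, an oestrogen receptor-positive human breast cancer line. The design asks where the protein sits on DNA in each line. Each line had 2 biological replicates, but the border caller had merged them into 1 list per line. The values below therefore carry no replicate spread, and no difference between the lines could be tested against replicates. The read depth behind each list is unknown.

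The Hs700T list held 746272 border pairs on chromosomes 1 to 22 and X, and the MCF-7 list held 932587, which was 1.25 times as many. Lone borders made up nearly all of both lists. In Hs700T 363902 were lone forward borders and 365340 lone reverse borders, and in MCF-7 there were 454887 and 456770. Matched pairs, with a border called on each strand, numbered 17030 in Hs700T (2.28%) and 20930 in MCF-7 (2.24%). Their median width was 57 bp in Hs700T (quartiles 31 and 79 bp) and 58 bp in MCF-7 (quartiles 32 and 79 bp).

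The order of the lines turned with the p limit. The median p of a pair was 0.0117 in Hs700T and 0.0188 in MCF-7. At a p of at most 0.01 Hs700T kept 317515 pairs and MCF-7 188926, and at 0.001 they kept 3812 and 1385, so that MCF-7 had 0.595 and 0.363 times as many as Hs700T. The lowest p of a lone border was 0.00503 in both lists. It was reached by 17.02% of all Hs700T pairs and by 3.752% of MCF-7 pairs. All pairs of p at most 0.001 were matched pairs.

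Matched pairs were concentrated in the densest regions of both lines. In the decile of 1 Mb windows with fewest lone borders, Hs700T had 0.749 matched pairs per 100 lone borders and MCF-7 had 1.08. In the densest decile the values were 4.79 and 4.31. The number of matched pairs per window rose with the number of lone borders to the power 2.11 ± 0.068 in Hs700T (jackknife error over chromosomes, 2868 windows) and 2.26 ± 0.11 in MCF-7 (2871 windows).

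**Figure D1:**
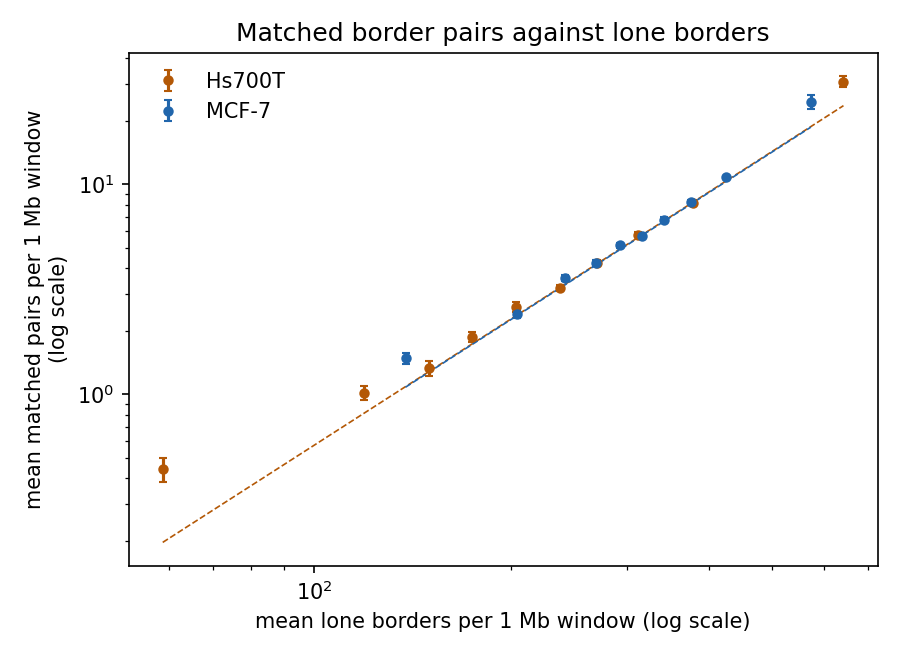
Mean matched pairs per 1 Mb window (log scale) against mean lone borders per 1 Mb window (log scale), in deciles of windows by lone borders, for Hs700T (orange) and MCF-7 (blue). Bars are the standard error over the windows of a decile, and dashed lines rise with the power 2 through the middle of each series. The highest deciles reach 30.8 matched pairs in Hs700T and 24.7 in MCF-7.

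A minority of the border pairs of each list overlapped a pair of the other list, and more than regional density alone would give. As the replicates were merged, the share that lists of the same line would have in common is unknown. A low share therefore does not show that few binding sites are common to the lines. Of the Hs700T pairs, 15.6% ± 0.12 (jackknife error over 598 blocks) overlapped an MCF-7 pair, against 5.53% after shifts of 1 to 10 kb and 4.51% after circular shifts. Of the MCF-7 pairs, 12.5% ± 0.24 overlapped an Hs700T pair, against 4.42% and 3.62%. Other planned overlap rules gave lower shares. With an overlap of at least 50% of both pairs they were 9.85% of Hs700T and 7.88% of MCF-7 pairs, 3.64 times the value after local shifts in both. With centres within 10 bp they were 3.89% and 3.12%, 4.59 and 4.60 times that value. The share thus depends on the overlap rule, and most intervals have a width set by the caller. The observed shares exceeded every one of the 100 local shifts (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). At the stricter p limits and in the strong set the shared share was lower and stayed above that after local shifts. Among pairs of p at most 0.01 it was 2.59% of Hs700T and 4.37% of MCF-7 pairs, 2.66 and 2.68 times the value after local shifts against 2.83 for all pairs of either line, and in the strong set it was 1.07% in both, 10.1 and 10.5 times the value after local shifts. At a p of at most 0.001, 6 pairs of each list overlapped, 40 times that value in Hs700T and 23.1 times in MCF-7. The strong set and the pairs of p at most 0.001 hold matched pairs only, because no lone border had a p below 0.00503. Their higher fold therefore cannot be told apart from that of matched pairs as a class, 10.8 in Hs700T and 10.7 in MCF-7.

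Sharing was mainly between borders of the same strand. Lone forward borders of Hs700T overlapped lone forward borders of MCF-7 in 12.77% of cases, 4.71 times the value after local shifts, and lone reverse borders overlapped lone reverse borders in 13.01%, 4.77 times that value. Lone forward borders overlapped lone reverse borders of the other line in 2.301%, which was 0.856 times the value after local shifts. This deficit may come from the classes, which was not tested. Inside a list, lone borders of opposite strand lay within 100 bp of each other only 78 times in Hs700T and 76 times in MCF-7. With every border counted, 16635 MCF-7 reverse borders lay within 100 bp of Hs700T forward borders against 15925 expected. Among pairs of p at most 0.01 there were 2164 against 1370, and 4578 against 1347 for forward borders of both lines.

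Many borders fell on the same base in both lines. Forward borders coincided 1605 times, against a mean of 79.0 and a maximum of 104 after local shifts, a 20.3-fold excess. Reverse borders coincided 1634 times, against a mean of 80.1, which was 20.4-fold. The excess of coinciding forward borders was found on 23 of 23 chromosomes, from 11.5-fold to 56.4-fold. It involved 0.421% of the Hs700T forward borders. Around the exact base the same-strand excess fell off over about 100 bp, and within that distance on either side 60152 forward borders of the lines lay together against 16050 expected. Inside each list, borders of the same strand were rare at that distance. Forward borders lay within 100 bp of each other 253 times in Hs700T and 587 times in MCF-7, and reverse borders 255 and 575 times. Whether this spacing sets the width of the excess was not tested.

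**Figure D2:**
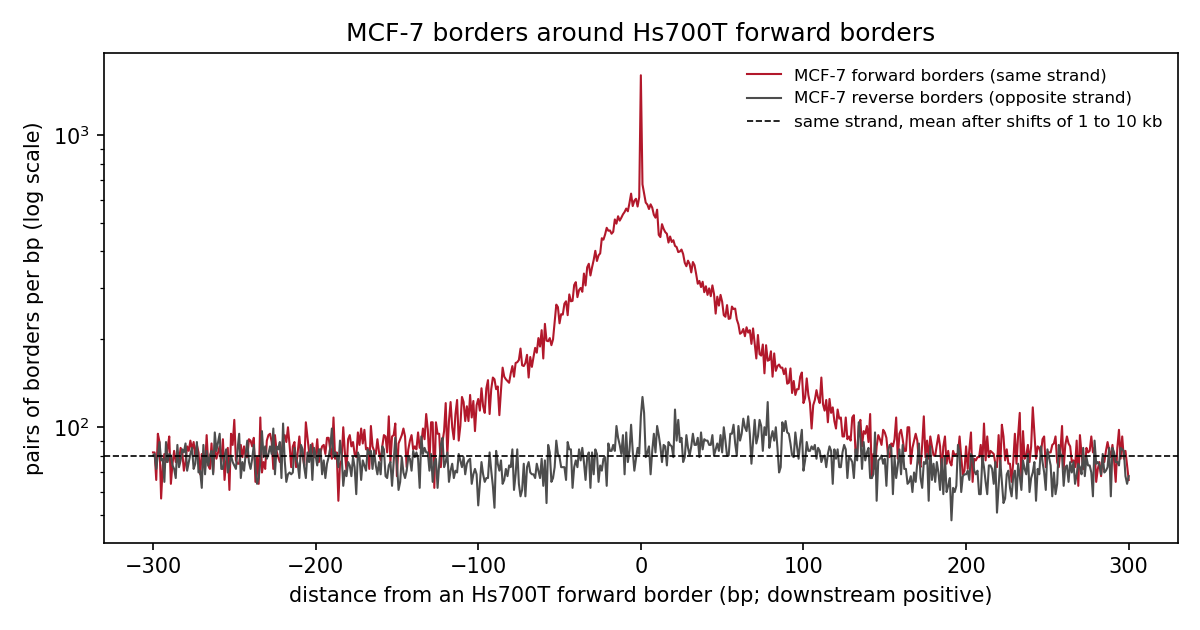
Number of MCF-7 borders at each distance (bp) from Hs700T forward borders, on a log scale, for borders of the same strand (red) and of the opposite strand (grey). The dashed line is the same-strand mean after shifts of 1 to 10 kb. Same-strand borders peak at 1605 at distance 0, where 109 opposite-strand borders were found.

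Matched pairs were also shared. Of the Hs700T matched pairs, 357 (2.10%) overlapped a matched pair of MCF-7, 10.8 times the value after local shifts. Of them, 10 had both borders within 2 bp of those of a matched pair in the other line, against a mean of 0.08 and a maximum of 1 after local shifts, and 27 had both within 5 bp. These 10 were looked at after the data were seen, and no region that is hard to map had been left out. Of them, 5 lay near the centromeres of chromosomes 1, 8, 10 and 19. The one of smallest Hs700T p lay near the centromere of chromosome 19, at 27733191 to 27733266. It had identical ends in both lines, a p of 0.000694 in Hs700T and 0.00111 in MCF-7. A further pair lay on the long arm of chromosome 8 at 139893825 to 139893899 in Hs700T and ended at 139893901 in MCF-7. What lies at these positions in an hg19 annotation was not analysed here.

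Pair density along the genome was alike in broad outline and differed in blocks. Over 2880 windows of 1 Mb the median was 222 pairs in Hs700T and 309 in MCF-7. Counts of the lines correlated across windows with a Spearman rho of 0.85, although windows are not independent replicates. With matched pairs alone it was 0.61 over the same windows, which held a median of 3 in Hs700T and 5 in MCF-7. After scaling by the list totals, 14 windows differed by over 4-fold, all with more pairs in MCF-7, and 9 of these lay on chromosome 3. With ratios scaled by the median window instead, 9 windows did so, all higher in MCF-7. By over 2-fold, 224 windows were higher in MCF-7 and 33 in Hs700T, or 165 and 80 when the ratios were scaled by the median window, which lay 0.13 above 0 on the log2 scale. In the 747 windows with at least 10 matched pairs in the higher line, matched pairs alone were higher in MCF-7 in 75 and in Hs700T in 33 by over 4-fold, and in 183 and 186 by over 2-fold.

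**Figure D3:**
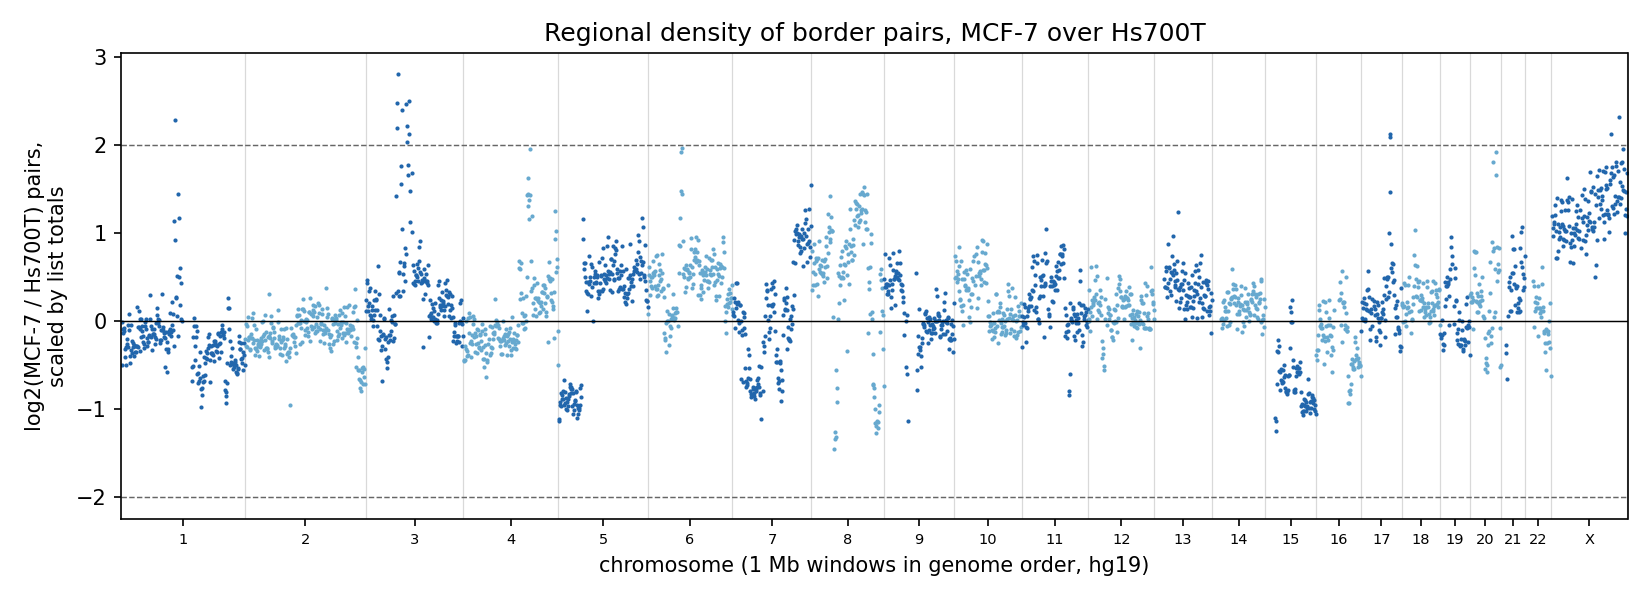
Scaled log2 ratio of border pairs, MCF-7 over Hs700T, in 1 Mb windows (points) along chromosomes 1 to 22 and X of hg19. Dashed lines mark 4-fold. The highest point, on chromosome 3 at 64 to 65 Mb, is 2.81, and the lowest, on chromosome 8 at 46 to 47 Mb, is -1.45.

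The windows with the highest ratio were of 2 kinds. At 62 to 65 Mb of chromosome 3, in a band known to be amplified in MCF-7, MCF-7 was dense: the window at 64 to 65 Mb held 1510 MCF-7 pairs and 172 Hs700T pairs, a scaled 6.99-fold difference (log2 2.81, 95% interval 2.58 to 3.05). The window at 107 to 108 Mb of chromosome 1 held 1062 against 174 pairs. Further along chromosome 3 Hs700T was sparse instead. At 82 to 91 Mb it had 39.9 pairs per Mb and MCF-7 had 194, a 3.90-fold scaled difference (95% interval of the log2 ratio 1.80 to 2.13). The window at 73 to 74 Mb held 28 Hs700T and 190 MCF-7 pairs.

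The windows with most MCF-7 pairs lay mainly on chromosomes 17 and 20. At 52 to 53 Mb of chromosome 20 there were 1903 MCF-7 and 401 Hs700T pairs, and at 59 to 60 Mb of chromosome 17 there were 1759 and 321. The run of adjacent windows over 2-fold apart at 56 to 60 Mb of chromosome 17 was 3.29-fold higher in MCF-7 (log2 1.72, 95% interval 1.63 to 1.81). Runs of at least 3 such windows numbered 19 with MCF-7 higher, over 174 windows. Of these runs 8, with 103 of the windows, lay on chromosome X. The median window of chromosome X held 51 Hs700T and 157 MCF-7 pairs. Its median log2 ratio of 1.22 (2.33-fold) was the highest of any chromosome and itself over 2-fold. The 8 runs there are thus parts of a chromosome-wide difference and cannot be counted as separate blocks. The 19 runs included 86 to 103 Mb of chromosome 8 (2.40-fold) and 65 to 70 Mb of chromosome 6 (2.97-fold). They also included 128 to 136 Mb of chromosome 4 (2.78-fold) and 107 to 155 Mb of chromosome X (2.81-fold).

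Chromosome 8 held the 10 windows with most Hs700T pairs, from 1226 to 1888. The densest, at 129 to 130 Mb, had 1888 Hs700T and 1059 MCF-7 pairs. It lies in the 8q24 band, which also carries the MYC oncogene, and whether MYC lies in this window was not analysed. This window and that at 128 to 129 Mb, with 1097 MCF-7 pairs, were also among the 10 with most MCF-7 pairs. Density there was thus high in both lines, against a median window of 309 pairs in MCF-7. Hs700T was higher in 4 runs, over 18 windows. On chromosome 8 they were 46 to 50 Mb (2.47-fold, log2 -1.31, 95% interval -1.38 to -1.23) and 129 to 137 Mb (2.25-fold), and on chromosome 15 they were 20 to 23 Mb (2.19-fold) and 74 to 77 Mb (2.05-fold). Of the 10 windows with the lowest ratio, 9 lay on chromosome 8, and the window at 21 to 22 Mb of chromosome 15 was the other.

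The smallest p value was 0.000293 in both lists. Fisher's method of combining p-values gives this for 2 values of 0.00503, the lowest p of a lone border. Read from the values only, it thus looks like a floor of the scoring and does not grade the windows. It was shared by many windows, 322 in Hs700T and 26 in MCF-7, so that the number of pairs decided which were named. In Hs700T these were led by 135 to 136 Mb of chromosome 8 with 1221 pairs and 91 to 92 Mb of chromosome 15 with 1051. In MCF-7 they were led by 63 to 64 Mb of chromosome 15 with 512 pairs, where Hs700T had 585.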

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

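Pairs on the mitochondrial genome stood outside the comparisons and lay above the 3 that a count of 0 would allow. Hs700T had 31 such pairs and MCF-7 had 35, of which 5 and 1 were matched pairs. This came to 2.08 and 2.17 pairs per kb, beside 0.222 and 0.309 per kb in the median nuclear window. The mitochondrial values are per kb from the first to the last pair, 14.9 kb in Hs700T and 16.1 kb in MCF-7. The nuclear values are per full window. No explanation was tested.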

How the results depend on the processing

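Comparisons by class of pair, of borders at the same base, of slopes and of runs, and the settings with matched pairs alone or median scaling, were chosen after the files had been opened. Every planned setting kept the shared share above all local shifts in both lines, from 0.157% of Hs700T pairs (p at most 0.001) to 15.6%. The share turned below the shifts only for lone forward against lone reverse borders, 2.301% and 1.834%. Lone borders of opposite strand were rare near each other inside a list too, and whether this gives the deficit was not tested. Stricter p limits left 317515 and 188926 pairs (0.01) and 3812 and 1385 (0.001) in Hs700T and MCF-7, ratios of 0.595 and 0.363 that turned the order of the lines, and the cause was not tested. Merging overlapping pairs gave 743449 and 928855 regions. Windows over 4-fold apart, all higher in MCF-7 on all pairs, numbered 1 with 5 Mb windows (MCF-7 higher), 1 at a p of at most 0.001 (Hs700T higher), 108 with matched pairs alone (75 with MCF-7 higher, 33 with Hs700T higher) and 9 with median scaling (all MCF-7). Those over 2-fold apart numbered 49 with 5 Mb windows (45 and 4), 3 at a p of at most 0.001 (all Hs700T) and 369 with matched pairs alone (183 and 186). The 5 Mb count is taken over 598 windows, that of matched pairs over 747 and that at 0.001 over 3, which only Hs700T brought to 10 pairs, so the direction there decides nothing. The excess of borders at the same base lay between 20.3-fold and 24.6-fold. The slope of matched pairs in MCF-7 fell from 2.26 to 1.98 without the densest windows. Of 49 named windows and 23 runs, median scaling turned 1, the window at 102 to 103 Mb of chromosome 12, from 0.10 to -0.027. Of the 37 named windows with 10 matched pairs in the higher line, matched pairs alone turned 3: 63 to 64 Mb of chromosome 15 (from -0.51 to 0.87), 37 to 38 Mb of chromosome 20 (-0.13 to 0.29) and 2 to 3 Mb of chromosome 4 (-0.44 to 0.050), each from at most 17 matched pairs per line, and the cause was not tested. The intervals on all pairs included 0 for those of chromosomes 12 and 20. No paired analysis was possible because the replicates of a line were merged before deposit, and leaving out a replicate was not possible for the same reason. Alternatives for promoters, gene lists, annotation classes, sequence and repeats were not run, for want of an hg19 genome or annotation. Depth is unknown, so a low count at a strict limit does not show fewer sites.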

Other observations

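The bound for 17q23 and 20q13, regions fixed beforehand, the tests of chance pairing as the whole source, of the share of opposite-strand borders and of borders carried over by pairing, and the looks at chromosomes 5, 8 and 15, at identical intervals and at border spacing, were chosen only after the values were seen. The bounds of the other tests were set before the values they measure were seen, although that of the covered interval was set once the spacing inside each list had been seen.

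The ratio between the lines differed between the arms of chromosome 5 as well as at short blocks elsewhere. On chromosome 5 the median window held 790 Hs700T and 524 MCF-7 pairs on the short arm (log2 -0.90) and 169.5 and 304.5 on the long arm (log2 0.51). The ratio was below 0 in 46 of 46 windows of the short arm and above 0 in 130 of 130 windows of the long arm, and the arms are told apart mainly by Hs700T. Chromosome 15 had a median log2 ratio of -0.78, with 568 pairs per window in Hs700T, 2.56 times its genome median, and 464 in MCF-7. On 8q24 the ratio ran from -1.27 to 1.00, with 12 of 30 windows above 0.

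Of the 10 matched pairs with both borders within 2 bp in the other line, 5 lay near the centromeres of chromosomes 1, 8, 10 and 19. One was the pair at chromosome 1, 121484069 to 121484137, identical in both lists, and 1 the pair at chromosome 8, 43794782 to 43794857. In all, 9 intervals of any class were identical in both lists, against a mean of 0.19 and a maximum of 2 after local shifts. Most of these also lay near centromeres: those on chromosomes 1, 8 and 10, and those starting at 27733191 and 27737466 of chromosome 19. All 3 matched pairs with both borders identical in both lists were among them. The only one made of lone borders in both lists lay at chromosome 19, 8576759 to 8576833, with a p of 0.0139 in Hs700T and 0.0120 in MCF-7. As the fixed widths of lone borders differ between the lists, an interval of lone borders in both needs another width in at least 1 list (3143 lone borders in Hs700T, 8739 in MCF-7), so this does not show how often lone borders coincide. ZNF414 is also on chromosome 19, and the transfected plasmid carries it. Whether this interval lies in the gene, and whether it comes from the plasmid, was not analysed here.

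Inside each list, reverse borders lay 1 to 100 bp downstream of forward borders 2.24 ± 0.026 times as densely as from there to 300 bp in Hs700T and 2.46 ± 0.033 times in MCF-7. The format of the lists puts the reverse border of a matched pair downstream, and only 173 lay 1 to 100 bp upstream in MCF-7, so this spacing is shaped by the caller.

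Regional differences in pair density between the lines are the first pattern, and independent change of single sites is argued against by the correlation of neighbouring windows, 0.89. Copy number may contribute to blocks at 17q23 and 20q13, regions known to be gained in MCF-7: their medians were 1.17, with 6 of 6 windows above 0, and 0.57, with 16 of 22, although 20q13 falls to 0.44 with median scaling. A gain of arm 1q in MCF-7 was not seen relative to Hs700T, as 1q minus 1p was -0.25 ± 0.079, and with 1q over 1p at 1.502 in MCF-7 and 1.848 in Hs700T a gain carried by both lines would be missed. At 21 to 22 Mb of chromosome 9, the window set for the deleted CDKN2A region, MCF-7 had 205 pairs. This was 0.62 of the chromosome median (95% interval 0.54 to 0.71) but 0.93 of the median of its 10 neighbours (221.5, from 188 to 253). Neither bound set beforehand was met and Hs700T had 0.53 of its own chromosome median, so this decides neither way. No drop confined to the window was seen, but a loss of only part of the 1 Mb window could pass unseen. Copy number was not tested for the arms of chromosome 5 or for chromosomes 15 and X as a whole, and stays open there. The same holds for the blocks at 62 to 65 Mb of chromosome 3 and 107 to 108 Mb of chromosome 1. No input library or karyotype was used here, and a difference in binding between the tissues was not tested and stays open.

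The number of matched pairs is the second pattern. Chance pairing of unrelated borders predicts a rise with the power 2 of lone borders, and the lower of the slopes was 2.11 ± 0.068 (Hs700T), which does not say how many pairs arose so. As the whole source, chance pairing cannot be told apart from pairs bounding a protein: reverse borders were 2.24 times as dense near as far in Hs700T, so the far density gives less than 50% of those nearby, but the caller shapes this spacing. Matched pairs overlapped those of the other line 10.8 times as often as after local shifts in Hs700T, and what gives this overlap was not tested. A protein whose binding rises with density, and other biological explanations, were not tested.

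Borders at the same base are the third pattern, and regional density alone is argued against, as the count was 15.4 times the highest of the local shifts. Loosely placed enrichment is argued against for the exact base only, where the excess was 5.32 times that at 11 to 50 bp. Within 100 bp, 60152 forward borders lay together against 16050 expected, and 1605 of them at the exact base. Most of the same-strand excess thus lay off that base. Inside each list, borders of the same strand were also rare within 100 bp of each other. Whether the caller sets the width of this excess was not tested. Covered intervals of up to 150 bp as the source of most shared borders cannot be judged. The opposite-strand excess downstream was 0.025 ± 0.0034 of the same-strand excess. However, lone borders made up 97.7% of the Hs700T and 97.8% of the MCF-7 list. The caller also left few lone borders of opposite strand near each other. The low value may thus be set partly by the caller and speaks only against intervals with both borders called. Among pairs of p at most 0.01 the value was 0.23 ± 0.019, with an excess of 333 upstream too, and the bounds leave covered intervals open. That limit itself favours matched pairs. They made up 5.17% of the Hs700T and 10.2% of the MCF-7 pairs kept, against 2.28% and 2.24% of all. The opposite-strand excess of all borders, 2228 ± 402 border pairs downstream against -1119 upstream, has the side a covered interval predicts, but so have shared same-strand borders carried over by the pairing inside MCF-7 alone, the form tested first (1441 ± 197 and -1219), or inside both lists, added after that was seen (2928 ± 444, of which the excess was 0.76 ± 0.065, and -2419). The first falls 787 ± 294 short downstream and the second misses the upstream value by 1300 ± 264, and as the overlap of the paths was not measured, the covered interval and the work of the caller cannot be told apart. Bias in mapping or sequence common to ChIP-exo libraries stays open, because 0 input or unrelated libraries were used here, and so does ZNF414 binding that leaves 1 border. Most of the intervals identical in both lists lay near centromeres, and how well reads map there was not analysed.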
